A study of Mus musculus with 7 samples.

How the data were processed

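Gene expression was measured in lesional skin of male mice on Affymetrix arrays, with 1 array for each of 7 samples. Per the labels' protocols, total RNA was extracted on silica columns with DNase digestion and was converted to biotinylated sense-strand target with the manufacturer's whole-transcript kit. The samples were 4 from OX40L knockout mice and 3 from OX40L wild type mice, grouped by the genotype in the sample titles, and all came from animals 9 weeks old given bleomycin for 3 weeks. Both genotypes are labelled as C57BL/6.

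The values are log2 expression values that the authors deposited after robust multi-array averaging (RMA), per the submitters' processing notes. As usually run, RMA subtracts a modelled background, normalizes probes between arrays by quantiles and summarizes the probes of a set by median polish, which can return exactly the same value on several arrays. The deposited values still differed in distribution between arrays, with medians from 3.45 to 3.74 and SDs over probe sets from 1.22 to 1.72. The RMA version, the probe-set definition and any genome build were not given in the sources used here. The scanner files were not used here. The values were taken as deposited and were not normalized again in the tests reported first.

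The value table held 25206 probe sets. Of these, 23185 had 1 gene symbol in the platform annotation, 0 had several symbols and 2021 were unnamed here. All 23185 named probe sets were found in a RefSeq gene table of assembly GRCm38.p6 by their Entrez number, and the table was used only for names and for which genes neighbour each other. No gene had more than 1 probe set, so no rule for merging probe sets was needed. No filter on dim probe sets was applied in the tests reported first.

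Genotypes were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on a 2-group design of all 7 arrays, with two-sided tests and Benjamini-Hochberg adjustment over the 23185 genes at a threshold of 0.05. Differences are knockout minus wild type on the log2 scale, with limma's standard error (SE) and 95% confidence intervals. Gene lists were compared with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 37 lists, each of which had at least 5 measured genes. Camera compares a list with all other genes. It was repeated with a correlation estimated for each list, and fry was run as a test of each list on its own. A list score per array was the mean over the list's genes of each gene's deviation from its mean over the 7 arrays. Scores were compared by a two-sided exact permutation test over the 35 splits of the 7 arrays into groups of 4 and 3, for which the smallest possible p is 0.0286. Figures were drawn with matplotlib 3.10.9, and tables were prepared with Python 3.11.15.

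The lists, the tests and the rule for naming genes were fixed before the data were examined. Named genes were Tnfsf4, Tnfrsf4 and 6 common readouts of fibrosis (Col1a1, Col1a2, Col3a1, Acta2, Tgfb1 and Ccn2). To these were added the 12 largest differences in each direction among genes with an adjusted p under 0.05 whose genotypes did not overlap, filled up from genes with an unadjusted p under 0.01 whose genotypes did not overlap. Predicted genes, olfactory and vomeronasal receptors, small RNAs and immunoglobulin or T cell receptor segments were left out of that part, after which 21 higher and 16 lower genes were eligible. For each list described, up to 4 members with the smallest p were also eligible. Some list members were found under a current symbol, such as Ccn2 for Ctgf and Epb42 for Epb4.2.

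The labels do not say whether each sample came from a different animal. The p-values therefore measure the spread between these samples, which may be partly technical. The number of arrays limits the precision. The sample descriptions also carry codes whose meaning is not stated in the labels. Wild type replicates 1 and 2 share the number 17, knockout replicates 1 and 2 the number 16, and wild type replicate 3 and knockout replicate 3 the number 18. The last 2 differ in genotype, so a shared number does not always stand for 1 animal, but whether it does for the other pairs is not known. If it did, the n of 3 and 4 given here would count samples from fewer animals. The number and the suffix of these codes were tried as blocks.

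The alternatives were an intensity trend with robust moderation, both changed in the same run, and filters on the dimmest 30% or 50% of genes. Others were quantile normalization again, centring on array medians, array weights, and the replicate number or the code as a block. Scores of muscle, hair follicle or adipocyte genes as covariates, all probe sets, an unadjusted threshold with a 1.5-fold change, and leaving out each array in turn were also run. A run without wild type replicates 1 and 3 and a run with the spread of each array's values as a covariate were added after seeing the data.

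The procedure was tested on simulated data with the number of genes, arrays and groups of the comparison of knockout with wild type. In 5 runs on 23185 genes, 50 genes at each size were changed per run. The simulated test recovered 29.6% of genes changed by 1 on the log2 scale, 73.2% of those changed by 2, 89.6% of those changed by 3 and 95.6% of those changed by 4. Of 763 gene calls, 41 were false. In the same simulated comparison, 19 of 20 lists shifted by 0.5 were recovered, and 1 other list was called. The simulated noise was independent between genes and had the same SD in both genotypes. In the data, estimated correlations within lists reached 0.771 (cell cycle), and the median SD was 0.387 in wild type and 0.188 in knockout. These simulated rates therefore do not show how the tests perform on the data.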

Results

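Transcript levels were measured in lesional skin from bleomycin-treated male mice that carried or lacked OX40L. OX40L is the product of Tnfsf4, a costimulatory ligand whose receptor, OX40, is found on activated T cells. Repeated injection of bleomycin is a common way to induce fibrosis of mouse skin. The series title names protection from inflammation-driven fibrosis, and the comparison asks how skin expression differs with OX40L genotype under the same treatment. There were 4 knockout arrays and 3 wild type arrays. All samples were bleomycin-treated, so the response to bleomycin itself was not compared.

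The 7 arrays were not equally alike. Wild type replicate 2 and the 4 knockout arrays correlated with each other at Pearson's r of 0.956 to 0.969 across probe sets, which are not independent replicates. Pairs that included wild type replicate 1 or 3 had r of 0.761 to 0.914, and the lowest value was between those 2 arrays. The SD of the log2 values over all probe sets was 1.72 on wild type replicate 1 and 1.22 on wild type replicate 3, against 1.38 to 1.48 on the other arrays. Actb, the gene of cytoplasmic beta-actin, had a log2 value of 9.97 on wild type replicate 1, 6.90 on replicate 2 and 3.03 on replicate 3, while the knockout arrays lay between 5.71 and 7.01. This gene was chosen after its values were seen. The median SD of a gene within a genotype was 0.387 in wild type and 0.188 in knockout.

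**Figure D1:**
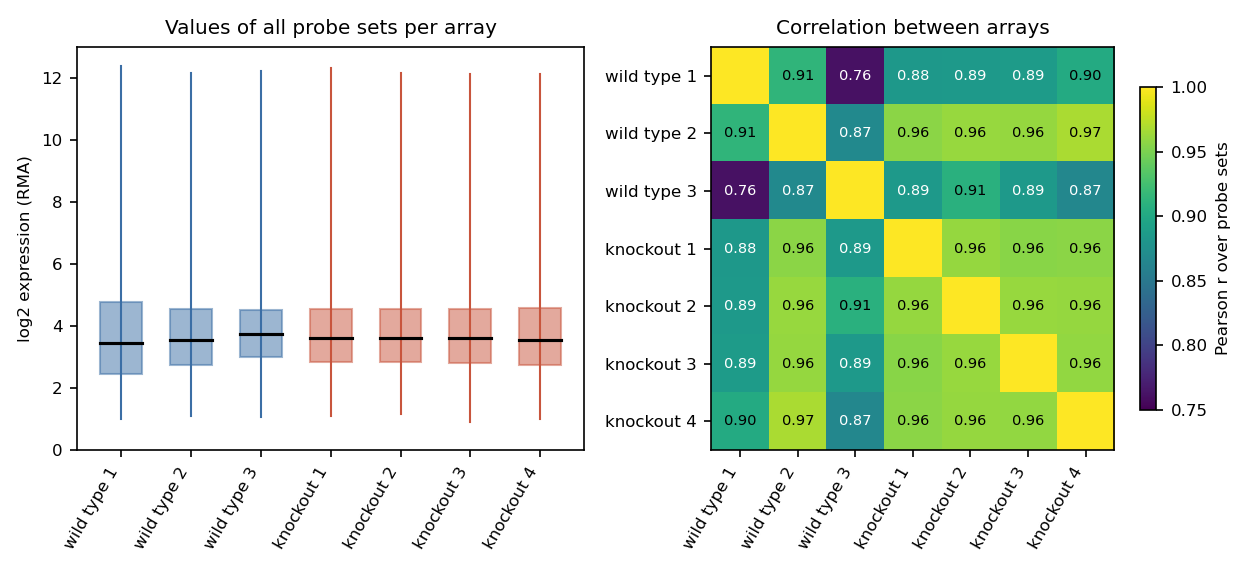
Left, log2 expression of all probe sets on each array, with the box from the lower to the upper quartile, the black line at the median and the thin line from the minimum to the maximum. Right, Pearson's r between arrays over all probe sets, in which wild type replicates 1 and 3 have r of at most 0.914 with any other array.

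Tnfsf4, the targeted gene, had similar values in both genotypes. Its log2 level was 2.95 ± 0.27 (SD, n = 4) in knockout and 2.93 ± 0.63 (SD, n = 3) in wild type, below the median of all values on these arrays, 3.60. The difference was 0.02 (SE 0.31, 95% confidence interval -0.70 to 0.74; limma adjusted p = 0.9995). The position of its probe set relative to the deleted part of the gene was not known here, so these values check nothing about the labels. Tnfrsf4, which encodes OX40, differed by -0.16 (SE 0.16, limma adjusted p = 0.9995). Its difference ran from -0.213 to -0.045 with single arrays left out.

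The common readouts of fibrosis did not differ by more than the spread between arrays. Col1a1 and Col1a2, which encode the chains of type I collagen, differed by 0.31 (95% confidence interval -0.76 to 1.38) and by -0.33 (-1.14 to 0.47). Col3a1, type III collagen, differed by -0.22 (-1.30 to 0.86), and Acta2, the smooth muscle actin of myofibroblasts, by -0.33 (-0.94 to 0.28). Tgfb1, the profibrotic cytokine, differed by -0.27 (-0.65 to 0.11), and Ccn2, a matricellular protein induced by TGF-beta, by 0.00 (-0.29 to 0.29). None of these 6 genes passed in limma at an adjusted p under 0.05, and the intervals leave room for differences of over 2-fold in Col1a1, Col1a2 and Col3a1. The sign of the Col1a1 difference turned without wild type replicate 3 (-0.30), and that of Col3a1 turned without wild type replicate 1 (0.25). Acta2 and Col1a2 moved to -0.044 and -0.009 without wild type replicate 1 and were at -0.555 and -0.582 without replicate 3, and Tgfb1 ran from -0.371 without wild type replicate 2 to -0.162 without replicate 3.

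Hbb-b1, which encodes an adult beta-globin chain of haemoglobin, was the only gene that passed the test, and it was higher in knockout skin. Its log2 level was 9.78 ± 0.42 (SD, n = 4) in knockout and 6.50 ± 0.14 (SD, n = 3) in wild type, a 9.70-fold difference (95% confidence interval 6.53 to 14.4). The 4 knockout arrays lay between 9.27 and 10.28, and the 3 wild type arrays between 6.34 and 6.62. The difference of 3.28 (SE 0.24) had a limma adjusted p of 0.0468. Probes of near-identical beta-globin genes can cross-hybridise, so the value belongs to the probe set, 15129_at. The difference stayed between 3.11 and 3.45 when single arrays were left out, but the adjusted p was then 0.546, 0.687 and 0.226 without wild type replicates 1, 2 and 3, and 0.468, 0.0548, 0.111 and 0.509 without knockout replicates 1, 2, 3 and 4. With the code suffix as a block the difference was 3.27 and the adjusted p 0.309; among arrays whose code lacked the suffix, knockout was at 9.67 and 9.88 and wild type at 6.62 and 6.34, and among those with it, knockout was at 9.27 and 10.28 and wild type at 6.54.

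The other 11 genes named for higher values in knockout were chosen by size, from genes with higher values on every knockout array than on any wild type array. None of them passed the adjusted threshold (adjusted p = 0.9995 for each in limma). Defb8, a beta-defensin antimicrobial peptide, differed by 3.56 (SE 0.96), with knockout values from 5.34 to 9.46 and wild type values from 2.33 to 4.09. Lce1k and Lce1h, late cornified envelope genes, differed by 1.71 (SE 0.39) and 1.64 (SE 0.33), while the list of cornified envelope and epidermal barrier genes did not pass (14 higher and 11 lower, median 0.063, camera adjusted p = 0.494). The serpin Serpina3b differed by 1.86 (SE 0.32) and Serpinb6c by 1.18 (SE 0.22). Pdk4, a kinase that inhibits pyruvate dehydrogenase, differed by 1.23 (SE 0.24), Scd3, a stearoyl-CoA desaturase of sebaceous glands, by 1.21 (SE 0.31), and Cox7a1, a cytochrome c oxidase subunit of muscle, by 1.09 (SE 0.29). Pcdhgc4, a protocadherin, differed by 1.18, with means of 3.46 in knockout and 2.28 in wild type, below the median of all values. Rnase2b, a ribonuclease of the eosinophil family, differed by 1.10, and Ifitm6, an interferon-induced transmembrane family member, by 1.06. The list of eosinophil markers did not pass (6 higher and 2 lower, median 0.063, camera adjusted p = 0.462). Without wild type replicates 1 and 3, a run chosen after seeing the data, the differences were 0.44 for Cox7a1, 0.32 for Ifitm6 and 0.80 for Scd3.

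The 12 lower genes named by the same rule had smaller differences, and none passed the adjusted threshold (adjusted p = 0.9995 for each in limma). They ran from -0.84 (SE 0.24) for Bcr to -0.67 (SE 0.19) for Chmp3, a subunit of the ESCRT-III membrane-scission complex. Srsf10, a splicing factor, differed by -0.70, Seh1l, a nucleoporin, by -0.70, Pot1b, a telomere-binding protein, by -0.79, Alkbh1, a nucleic acid demethylase, by -0.69, and Ppp4r2, a regulatory subunit of protein phosphatase 4, by -0.81. Iscu, a scaffold for iron-sulfur cluster assembly, differed by -0.70, Dcun1d1, a neddylation factor, by -0.72, Hdhd2 by -0.83 and Chodl by -0.69. Chodl was at 3.41 to 3.76 in wild type and at 2.80 to 3.08 in knockout, the latter below the median of all values. Ugt1a6b, a glucuronosyltransferase, differed by -0.79 with values between 1.62 and 2.73, below the median of all values. Without wild type replicates 1 and 3, the differences were -0.51 for Bcr, -0.41 for Ugt1a6b, -0.40 for Srsf10 and -0.45 for Iscu, and without wild type replicate 1 alone that of Bcr was -0.56.

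**Figure D2:**
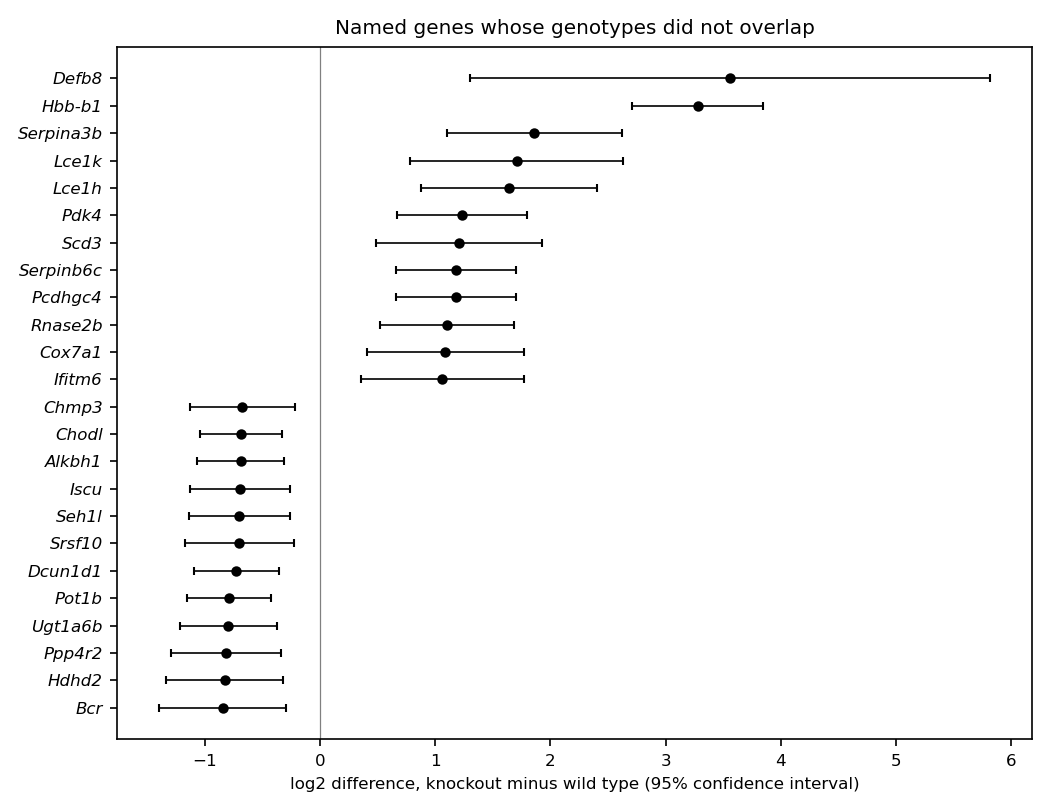
Log2 difference, knockout minus wild type, of the 24 genes named by size of difference, as points with 95% confidence intervals. Hbb-b1, at 3.28, has a narrower interval than Defb8, at 3.56, and is alone among the 24 in having an adjusted p under 0.05.

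Over all 23185 genes, 1 gene was higher in knockout and 0 were lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 436 genes, 238 higher and 198 lower, against 1159 that chance would give in independent genes. Of these, 239 differed by at least 1.5-fold, 141 higher and 98 lower. The genotypes did not overlap in 443 genes, 1.91% of those tested, whereas chance gives 5.71% for 3 arrays against 4. The unadjusted count moved by over 1.5 times without wild type replicate 1 (738), replicate 2 (807) or replicate 3 (2786), and without knockout replicate 1 (249) or 3 (259). Without both wild type replicates 1 and 3, a run chosen after seeing the data, 2024 genes had an unadjusted p under 0.05 and 0 passed the adjusted threshold, with the lone wild type array assumed to vary like the knockout arrays.

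Of the 37 gene lists, 10 passed camera with the preset correlation, 6 higher and 4 lower in knockout. With an estimated correlation, 0 of the 37 passed at an adjusted or an unadjusted p under 0.05. Fry called 0 lists after adjustment and 2 before it. The exact permutation test of list scores called 0 after adjustment and 1 before it, erythroid genes. Its smallest p of 0.0286 can hardly pass adjustment over 37 lists. Across all lists, Hbb-b1 was the only member that passed, both adjusted over the list alone and over all genes.

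Hair follicle keratin and cycle genes were lower in knockout, in 35 of 35 measured members, with a mean and a median difference of -1.31 (camera adjusted p = 5.88e-13; adjusted p = 0.709 with an estimated correlation). Krt25, an inner root sheath keratin, differed by -2.90 (SE 1.47), Padi3, a peptidylarginine deiminase of the follicle, by -1.24 (SE 0.61), and Krt33b, a hair cortex keratin, by -0.40 (SE 0.17). None passed adjusted over the list alone. The list score was 2.94 on wild type replicate 1 and -0.14 and -0.55 on the other wild type arrays, against -1.13 to -0.28 in knockout, and without wild type replicate 1 the mean difference was -0.22 (adjusted p = 0.130). Cell cycle genes were lower in 29 of 31 members, with a mean of -0.37 and a median of -0.39 (camera adjusted p = 1.34e-06; adjusted p = 0.709 with an estimated correlation). Plk1, a mitotic kinase, differed by -0.57 (SE 0.23) and Kif11, a spindle motor, by -0.52 (SE 0.32), and 0 members passed adjusted over the list alone or over all genes. The cell cycle score was 1.07 on wild type replicate 1 and -0.31 to -0.09 on the other 6 arrays, and without that array the mean difference was 0.061 (adjusted p = 0.370).

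Skeletal muscle genes were higher in 26 of 30 members, with a mean and a median difference of 0.43 (camera adjusted p = 1.34e-06; adjusted p = 0.709 with an estimated correlation). Cox6a2 and Cox8b, muscle isoforms of cytochrome c oxidase subunits, differed by 0.97 (SE 0.35) and 0.80 (SE 0.31), and Mylpf, a fast-fibre myosin light chain, by 0.62 (SE 0.30). Mitochondrial respiratory chain genes were higher in 20 of 29, with a mean of 0.255 and a median of 0.16 (camera adjusted p = 0.00530; adjusted p = 0.795 with an estimated correlation), Ndufs3 of complex I differing by 0.65 (SE 0.19). Sebaceous gland and epidermal lipid genes were higher in 13 of 18, with a mean of 0.31 and a median of 0.12 (camera adjusted p = 0.0157; adjusted p = 0.709 with an estimated correlation), among them Awat1, a wax synthase, by 0.98 (SE 0.34). In these 3 lists, 0 members passed adjusted over the list alone or over all genes. Wild type replicate 3, the array with the smallest SD over probe sets, had the lowest scores of the 7 arrays, -1.08 for muscle, -0.86 for the respiratory chain and -0.81 for sebaceous genes. Without it the mean differences were 0.013 (adjusted p = 0.923), -0.10 (adjusted p = 0.172) and -0.006 (adjusted p = 0.923). The respiratory chain call also ended without knockout replicate 4 (mean 0.18, adjusted p = 0.108), and the sebaceous call without wild type replicate 2 (mean 0.28, adjusted p = 0.132) or knockout replicate 4 (0.30, adjusted p = 0.0553).

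Collagen genes and TGF-beta genes were lower as groups by small amounts. Fibrillar collagen and collagen processing genes were lower in 19 of 28 members, with a mean difference of -0.12 and a median of -0.14 (camera adjusted p = 0.0379; adjusted p = 0.709 with an estimated correlation). Col12a1, a collagen that associates with fibrils, differed by -0.76 (SE 0.37) and Bmp1, a procollagen proteinase, by -0.48 (SE 0.24). TGF-beta signalling and myofibroblast genes were lower in 20 of 28, with a mean of -0.16 and a median of -0.078 (camera adjusted p = 0.0259; adjusted p = 0.709 with an estimated correlation). The members with the smallest p were Pmepa1, Smad7 and Bambi, negative regulators of the pathway, at -0.38 (SE 0.19), -0.47 (SE 0.24) and -0.37 (SE 0.21), and Smad2, a signal transducer, at -0.63 (SE 0.31). In both lists, 0 members passed adjusted over the list alone or over all genes. Scores on wild type replicate 1 were the highest of the 7 arrays, 0.34 for collagens and 0.45 for TGF-beta genes, and without it the mean differences were 0.018 (adjusted p = 0.848) and 0.019 (adjusted p = 0.922). The TGF-beta call also ended without knockout replicate 3 (mean -0.14, adjusted p = 0.0822), and the collagen call without wild type replicate 2 (mean -0.12, adjusted p = 0.130) or knockout replicate 1 (-0.092, adjusted p = 0.127), 2 (-0.11, adjusted p = 0.0842) or 4 (-0.11, adjusted p = 0.0553). Both calls ended when the dimmest 30% or 50% of genes were left out, with adjusted p of 0.157 and 0.332 for collagens and of 0.0907 and 0.0882 for TGF-beta genes in camera.

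Markers of NK cells and of mast cells and basophils were slightly higher in knockout. NK cell genes were higher in 12 of 14 members, with a mean difference of 0.21 and a median of 0.17 (camera adjusted p = 0.0263; adjusted p = 0.709 with an estimated correlation), and Ncr1, an activating NK receptor, differed by 0.55 (SE 0.22) and Gzma, a cytotoxic granule protease, by 0.75 (SE 0.32). Mast cell and basophil genes were higher in 11 of 14, with a mean of 0.16 and a median of 0.15 (camera adjusted p = 0.0344; adjusted p = 0.709 with an estimated correlation), while Cpa3, a mast cell carboxypeptidase, differed by 0.73 (SE 0.42) and Kit, the stem cell factor receptor, by -0.50 (SE 0.29). In both lists, 0 members passed adjusted over the list alone or over all genes. Cpa3 was at 5.49 on wild type replicate 3, against 6.86 and 7.37 on wild type replicates 1 and 2 and 7.09 to 7.56 in knockout. The NK score was -0.53 on wild type replicate 1 and 0.038 to 0.23 on the other 6 arrays. The NK call ended without wild type replicate 1 (mean 0.008, adjusted p = 0.848) or 3 (0.32, adjusted p = 0.0642) and without knockout replicate 1 (0.17, adjusted p = 0.129) or 4 (0.23, adjusted p = 0.0553). The mast cell call ended without wild type replicate 1 (mean 0.16, adjusted p = 0.0616) or 3 (0.091, adjusted p = 0.491) and without knockout replicate 1 (0.13, adjusted p = 0.0858), 2 (0.15, adjusted p = 0.0984) or 4 (0.18, adjusted p = 0.0553). It also ended without the dimmest 30% (camera adjusted p = 0.172) or 50% (camera adjusted p = 0.332) of genes.

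The erythroid list was higher in knockout in 4 of 5 members, with a mean difference of 0.71 and a median of 0.073 (camera adjusted p = 0.0157; adjusted p = 0.709 with an estimated correlation). Hbb-b1 was the 1 member that passed adjusted over the list alone and over all genes, and the next was Epb42, a red cell membrane protein, at 0.32 (SE 0.22). The other 4 members, Hbb-bs (0.006), Alas2 (0.073), Epb42 and Slc4a1 (-0.11), had mean values below the median probe set, and none of them separated the genotypes. The score with Hbb-b1 was higher on all 4 knockout arrays (0.22 to 0.39) than on all 3 wild type arrays (-0.53 to -0.21), with an exact permutation p of 0.0286, the smallest that 35 splits allow, and 0.930 after adjustment over 37 lists. This separation rested on Hbb-b1, since without it the score differed by 0.074 (exact permutation p = 0.514), with knockout at 0.008 to 0.053 and wild type at -0.219 to 0.242, a score added after seeing the data. The camera call ended without wild type replicate 1 (mean 0.66, adjusted p = 0.105) or 2 (0.68, adjusted p = 0.124) or knockout replicate 4 (0.71, adjusted p = 0.0553).

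**Figure D3:**
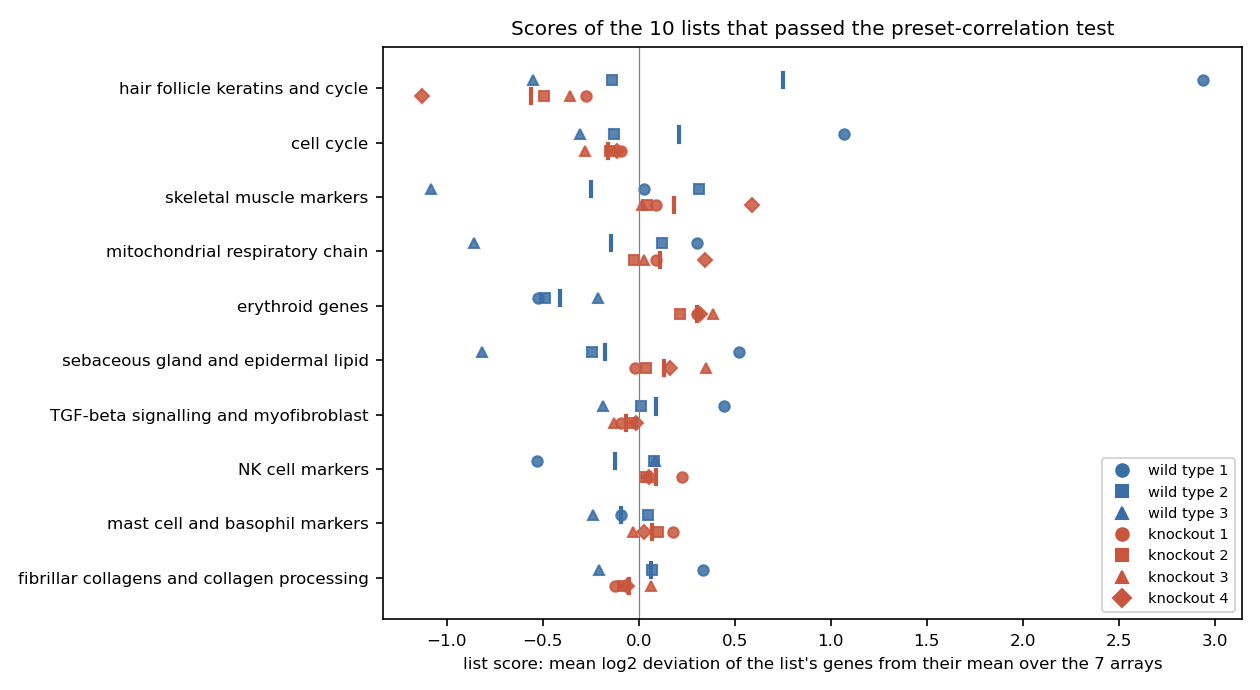
Score per array, the mean log2 deviation of a list's genes from their mean over the 7 arrays, for the 10 lists that passed camera with a preset correlation. Points are arrays, with wild type in blue and knockout in red, and vertical bars are genotype means. Of these lists the genotypes separate only for erythroid genes, through Hbb-b1 alone, while wild type replicate 1 stands at 2.94 for hair follicle genes and wild type replicate 3 at -1.08 for skeletal muscle genes.

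The T cell lists did not pass. T cell markers had a median difference of 0.037 (camera adjusted p = 0.574), and the receptor component Cd3d differed by 0.58 (SE 0.18) and the adaptor Trat1 by -0.59 (SE 0.20). Cd3d had means of 3.42 in knockout and 2.84 in wild type, and Trat1 of 2.24 and 2.83, all below the median of all values. Activation, costimulation and helper subset genes had a median of 0.10 (camera adjusted p = 0.144), and genes of the OX40L-OX40 pathway had a median of -0.089 (camera adjusted p = 0.144). B cell and plasma cell genes had a median of 0.10 (camera adjusted p = 0.288). Monocyte and macrophage markers had a median of -0.11 (camera adjusted p = 0.288), with Retnla, a marker of alternatively activated macrophages, at 1.36 (SE 0.49) and the integrin Itgam at -0.55 (SE 0.22). Neutrophil markers (median 0.047, camera adjusted p = 0.435), inflammatory cytokines (median 0.033, camera adjusted p = 0.153) and interferon-stimulated genes (median -0.005, camera adjusted p = 0.703) did not pass either. The median and the mean of the chemokine list differed in sign (0.063 and -0.006, camera adjusted p = 0.973, direction up), as did those of matrix proteases and inhibitors (0.027 and -0.028, camera adjusted p = 0.973, direction down). Extracellular matrix glycoproteins and proteoglycans had a median of 0.046 (camera adjusted p = 0.973), with Thbs2, a matricellular thrombospondin, at -0.61 (SE 0.20) and Mfap4, a microfibril-associated protein, at 0.67 (SE 0.27). No member of the lists in this paragraph passed adjusted over the list alone or over all genes.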

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

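Among 42 named values and list scores examined over the 4 knockout arrays, 8 had 1 array far from the other 3 by a test of the gap against the range; chance gives about 1 in 20. Wild type, with 3 arrays, was not examined in this way. Exactly equal values on several arrays, which the summarization can give, make such gaps easier to reach.

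Tnfsf4 was at 3.35 on knockout replicate 1 and between 2.81 and 2.82 on the other knockout arrays. Tgfb1 was at 4.86 on knockout replicate 4 and at 5.19 on the other 3. Ccn2 was at 4.95 on knockout replicate 2 and between 4.74 and 4.77 on the others. Pdk4 was at 8.16 on knockout replicate 4 and between 7.29 and 7.41 on the others. Scd3 was at 7.62 on knockout replicate 3 and between 6.67 and 6.68 on the others. Iscu was at 4.44 on knockout replicate 1 and between 4.69 and 4.70 on the others. The skeletal muscle score was 0.59 on knockout replicate 4 and 0.017 to 0.088 on the others. The NK cell score was 0.23 on knockout replicate 1 and 0.038 to 0.052 on the others.

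Among the 2021 probe sets that are unnamed here and entered none of the gene and list comparisons above, 50 had an unadjusted p under 0.05 and 0 an adjusted p under 0.05 in limma. The probe set 100503686_at, chosen after its values were seen, had the smallest p of these. It was at 11.25 ± 0.30 (SD, n = 4) in knockout and 8.91 ± 0.41 (SD, n = 3) in wild type, a difference of 2.34 (SE 0.25, limma adjusted p = 0.323 over all 25206 probe sets). All 4 knockout values, 10.94 to 11.64, lay above all 3 wild type values, 8.49 to 9.32. The order of the arrays within each genotype was that of Hbb-b1. Knockout replicates 3, 4, 1 and 2 were at 11.64, 11.33, 11.10 and 10.94 (Hbb-b1 at 10.28, 9.88, 9.67 and 9.27), and wild type replicates 1, 2 and 3 at 9.32, 8.93 and 8.49 (Hbb-b1 at 6.62, 6.54 and 6.34). Which gene it measures is not known here, so this does not decide what raised Hbb-b1.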

How the results depend on the processing

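The runs without wild type replicates 1 and 3 and with array SD as a covariate were chosen after seeing the data. The 24 genes named by size were chosen for genotypes that do not overlap, so leaving out arrays cannot turn their direction, and their signs in those runs say nothing about stability; 22 passed the adjusted threshold with array weights, where Cox7a1 was at 0.421 (1.089 as reported) and Ifitm6 at 0.303 (1.062 as reported). That run called 4032 genes (7364 unadjusted) and gave wild type replicate 2 a weight of 75.4 against 0.106 and 0.109 for wild type replicates 1 and 3, so its wild type mean rests on 1 array, and the weight estimation stopped before converging. The count of 1 adjusted gene held with the filters at 30% and 50% and with the code number as a random block. It was 0 with the intensity trend and robust moderation, quantile normalization, median centring or the code suffix as a block. With the muscle, hair follicle, adipocyte or array SD covariate, over all probe sets and in each leave-one-out run it was also 0. Over all alternatives the adjusted p of Hbb-b1 in limma ran from 0.00140 to 1. At an unadjusted p under 0.05 with a 1.5-fold change the count was 239. The unadjusted count, 436 as reported, was 219 without the dimmest 50% of genes (fewer were tested), 716 after quantile normalization, 278 with the code suffix, 1484, 810 and 1370 with the muscle, hair follicle and adipocyte covariates, 2024 without wild type replicates 1 and 3, 1767 with array SD, and 249 to 2786 with single arrays left out. The count of 10 lists was 7 with each filter, where the collagen, TGF-beta and mast cell calls ended and the erythroid list kept too few members to be tested. It was 6 after quantile normalization, 8 after median centring, 0 with an estimated correlation, 0 with fry and 4 to 15 with single arrays left out. Where no construction is named, the cause was not tested.

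With the replicate number as a block, 0 genes passed, 251 had an unadjusted p under 0.05 and 4 lists were called, and Ccn2 turned to 0.010. Same-numbered samples had deviations correlated at -0.086, -0.145 and 0.034 across genes. These values gave no sign of a pairing, but they cannot exclude that such samples share more than a number. No wild type sample correlated best with the knockout sample of its own number: wild type replicates 1 and 2 did so with knockout replicate 4 (0.266 and 0.181), and wild type replicate 3 with knockout replicate 2 (0.244).

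Tnfsf4 turned to -0.057 after quantile normalization, -0.081 with the code number as a random block, -0.211 with the hair follicle covariate and -0.099 with array SD, and ran from -0.178 to 0.382 with single arrays left out. Ccn2 turned to 0.067 after quantile normalization, 0.015 with array weights, 0.028 with the hair follicle covariate, 0.009 without wild type replicates 1 and 3 and 0.006 with array SD, and ran from -0.050 to 0.024 with single arrays left out. Col1a1 turned to -0.038 with array weights, -0.121 with the muscle covariate and -0.055 without wild type replicates 1 and 3 (-0.296 to 0.736 with single arrays left out). Col1a2 turned to 0.012 and Col3a1 to 0.402 with the hair follicle covariate, and Col3a1 ran from -0.781 to 0.252 with single arrays left out.

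With the hair follicle covariate, which sets its own list to 0 by construction, the mean turned to 0.113 for cell cycle, 0.045 for collagens and 0.039 for TGF-beta genes. The cell cycle mean ran from -0.627 to 0.061 with single arrays left out. The respiratory chain mean turned to -0.023 with array weights, -0.073 with the muscle covariate and -0.009 without wild type replicates 1 and 3, and ran from -0.101 to 0.480 with single arrays left out. Skeletal muscle turned to -0.150 with array weights and -0.130 without wild type replicates 1 and 3. In the latter run the hair follicle (-0.426, adjusted p = 0.0212), sebaceous (0.375, adjusted p = 0.0184) and erythroid (0.792, adjusted p = 0.0212) lists passed camera at the preset correlation, with the spread taken from the knockout arrays alone, while with an estimated correlation each had an adjusted p of 0.709 over all 7 arrays, so these calls say nothing about stability. NK genes, at 0.007 and 0.010 in those 2 runs, lay below the other genes, against which camera sets a list. After quantile normalization the calls of the NK, TGF-beta, erythroid, collagen and mast cell lists ended, and those of the hair follicle, cell cycle, muscle, respiratory chain and sebaceous lists did not. With the preset correlation and apart from leave-one-out, the mast cell list passed in 2 of 13 other settings, collagens in 4, NK and TGF-beta genes in 6 each, the respiratory chain in 8, cell cycle, muscle and sebaceous genes in 10 each, hair follicle genes in 12, and erythroid genes in 7 of 11.

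The exact permutation test called 0 lists after adjustment in every run. With 1 array left out its splits are too few to pass, so those runs say nothing about stability. With all 7 arrays, many of the 37 lists would have to reach the smallest p of 0.0286 for any to pass, so a count of 0 says little there too. The mean over several probe sets of a gene was not run, as no gene had more than 1, and camera was not run with the code number as a random block, which it does not take. Signal over background was not given, so what it limits was not tested.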

Other observations

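The tests of array range and of blood RNA for Hbb-b1, and all tests on single wild type arrays, were chosen only after the result was seen.

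Wild type replicate 1 carried a hair and pigment profile that no other array showed. Krt71, an inner root sheath keratin, was at a log2 level of 10.53 there and between 3.44 and 6.42 on the other 6 arrays, and Krtap3-1, a keratin-associated protein of the hair shaft, was at 8.60 against 3.16 to 4.81. Mlana, a melanosome protein, was at 9.37 against 4.32 to 5.30, and Dct, a melanin synthesis enzyme, at 8.02 against 3.91 to 4.25. These genes were chosen after their values were seen. The Schwann cell and melanocyte list as a whole had a median difference between genotypes of -0.23 and did not pass (camera adjusted p = 0.0935).

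In the cornified envelope and epidermal barrier list, which did not pass (camera adjusted p = 0.494), the smallest p were those of Lce1c at 0.81 (SE 0.33) and Lce1f at 0.67 (SE 0.27), both late cornified envelope genes. Genes that neighbour Tnfsf4 on chromosome 1 had a median of -0.13 and did not pass (camera adjusted p = 0.144). Fry gave this list a p of 0.0383 before adjustment and 0.708 after it. Gas5, a host gene of small nucleolar RNAs, differed by -1.28 (SE 0.45). It was at 7.05, 5.94 and 4.96 on wild type replicates 1, 2 and 3, and at 4.43 to 4.96 in knockout. Of the 40 named genes nearest to Tnfsf4, 5% had an unadjusted p under 0.05, a share above that of 82.3% of 570 windows of 40 genes. These were Gas5 and, in the other direction, Gm6177 at 0.92 (SE 0.33).

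Splits of the 7 arrays into 4 and 3 were counted for each result of the tests across genes. For genes at an adjusted p under 0.05, 1 of the 35 splits, the real one, gave as many as 1, and the highest of the others was 0. The share, 0.0286, is below 0.05 and is the smallest that 35 splits allow. Other counts were tested on the same splits, and samples that share a code number may not be independent. Chance is therefore less likely but not excluded for this count of 1 against 0, in the values as deposited and with all arrays. The limma call of Hbb-b1, at a difference of 3.277 (SE 0.243), ended after quantile normalization (3.223, SE 0.288, adjusted p = 0.138) and after median centring (3.264, SE 0.267, adjusted p = 0.0933). It also ended with an intensity trend and robust moderation, which were not tried apart (3.277, SE 0.364, adjusted p = 0.518). The difference hardly moved in these runs and the SE grew, but the count was then 0, so the result of the splits does not extend to them. The call also ended in every leave-one-out run, at differences of 3.11 to 3.45. For lists called by camera with the preset correlation, 25 of the 35 splits gave at least 10, and the highest other was 21, so chance cannot be excluded. For genes at an unadjusted p under 0.05, 22 of the 35 gave at least 436, and chance cannot be excluded either. The highest other, 3347, set wild type replicate 3 and knockout replicates 1, 2 and 3 against the rest. These 4 arrays had the smallest SDs over probe sets, 1.22 to 1.40, against 1.46 to 1.72 on the rest. That split thus parted the arrays by their SD and not by genotype, but what raised its count was not tested.

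Hbb-b1 was higher on every knockout array. The tables argue against differences in array range as the cause, since the gap between the genotypes exceeded the largest range within a genotype by at least 1.25 on the log2 scale in the deposited, median-centred and quantile-normalized values. More blood in the knockout samples stays open, since the other erythroid genes, Hbb-bs, Alas2, Epb42 and Slc4a1, had a median difference of 0.04 but 0 of these 4 lay above the median probe set, and the probe set 100503686_at, whose gene is not named here, ranked the arrays within each genotype as Hbb-b1 did. A different strain segment around the beta-globin genes may also be considered, because Hbb-b1 names a gene of the beta-globin haplotype found in strains such as BALB/c, whereas C57BL/6 carries Hbb-bs and Hbb-bt; 0% of the 40 named genes nearest to Hbb-bs had an unadjusted p under 0.05, but 36 of them are olfactory receptors and 31 lie below the median of all values, so this cannot be told apart from no segment. An effect of the OX40L genotype itself stays open and was not tested apart from these.

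The high hair follicle score of wild type replicate 1 was not explained by the wider range of that array. After quantile normalization the score still exceeded the highest other array by 2.62, against a range of 0.95 over the other 6, and the list's median deviation of 3.67 lay above all 10000 random lists matched on expression (-0.53 to 0.70). A follicle growth stage in that biopsy, when matrix cells divide and melanocytes make pigment, stays open as a candidate explanation. It was prompted by the pigment genes already seen to be high there, so their median deviation, above that of 6 Schwann cell genes by 2.616 against at most 0.519 on the other arrays, restates what was seen and cannot decide it. Whether genotype or the site of the biopsy set the stage was not tested.

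The muscle, sebaceous and respiratory chain scores were lowest on wild type replicate 3, the array with the smallest SD over probe sets. Range here means this spread of values, not the distance from minimum to maximum. The brightest 5% of genes in no list, 1006 genes, had a median deviation of -1.05 there and of 0 to 0.34 on the other arrays. After quantile normalization, which gives the arrays the same range, the 3 scores still differed from the lowest other array by -0.198, -0.481 and -0.391. Only for the respiratory chain was this gap larger than the width of the range of the other 6 (0.335). Camera at the preset correlation still called the 3 lists between genotypes (means 0.472, 0.430 and 0.302). Other splits of the arrays gave such calls too, so they cannot decide how far a lower range was the cause. A lower range stays open as a cause of the low scores. Less muscle and gland tissue may also have lowered them, though the keratinocyte and ribosomal protein scores were lowest there too. After quantile normalization these 2 scores lay below every other array, by -0.259 and -0.314. These gaps were smaller than the widths of the ranges of the other arrays (1.01 and 0.393), so they do not decide it. Reference genes, chosen after their values were seen, were also lowest on this array in the deposited values. Actb was at 3.03 (5.71 to 9.97 on the other arrays), Hprt at 3.71 (5.17 to 6.72) and Rps3 at 4.21 (5.21 to 7.98). Tbp was at 2.46 (3.04 to 3.68), Rplp0 at 6.40 (6.51 to 7.71) and B2m at 11.14 (11.95 to 12.13). Neither explanation was excluded for this array, and no other cause of its low values was tested.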
